A study of Mus musculus with 8 samples.

How the data were processed

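The labels describe lean wild-type C57BL/6 mice aged 2 months, kept on a 12 h light and 12 h dark cycle with free access to food, then fasted overnight before the liver was taken. Per the labels, RNA was extracted with Trizol, treated with DNase I and depleted of ribosomal RNA before sequencing. Per the submitters' processing notes, fastp 0.19.5, Bowtie2 2.2.9, GATK 3.8 and SAMtools 1.9 were used with the mm10 assembly. Which program aligned and which counted the reads, the gene annotation and the strandedness are not given in the sources used here.

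The authors deposited 1 table of estimated counts per gene (expected counts, not normalised), of whose values 10.9% are not whole numbers, and these were rounded. It has 56181 entries, of which 55536 carry a gene identifier and 645 are assembled loci without a gene name. The assembled loci hold 0.676 to 1.08% of the counts of a sample and were left out, except in an alternative that kept them. The authors also deposited a table of their own comparison, with a fold change of knockdown over control per gene, as deposited. The name under which that comparison was deposited gives DESeq2, but its version and any shrinkage of the folds are not given in the sources used here. For some genes with few or variable counts these folds lie nearer to no change than the fitted values (Apela 5.41, Moxd1 -6.25 and Eif4ebp3 -2.66 on the log2 scale). Its log2 values are the logarithms of those fold changes, a ratio per gene, as deposited. Its p-value and adjusted p-value columns are those of the authors' comparison, per the file headers, and the adjustment method is not stated there. Settings of that comparison are not given in the sources used here. Of its genes 3756 are marked as significant, all with an absolute log2 fold change of at least 1 and an adjusted p of at most 0.05, while 9087 have an adjusted p under 0.05.

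Each of the 8 columns of counts was assigned to its sample by the code in the sample's label. Positions are those of GENCODE mouse release 21, on the build that the submitters name, and 55450 of the gene identifiers were found in it. Total counts ranged from 24371461 to 32389444. Nothing in the labels says more than that the samples are separate, so p-values measure the spread between these samples. The lowest chi-square per degree of freedom between replicates of a group was 9.64, so replicates differed by more than counting error.

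Knockdown was compared with control in R 4.3.3 with edgeR 4.0.16: filterByExpr with default settings kept 15375 genes, normalisation factors were TMM, and glmQLFit and glmQLFTest gave p-values that were adjusted by the Benjamini-Hochberg method over the genes tested. A gene is said to have risen, fallen or changed where the adjusted p was under 0.05. CPM values were computed on the total count of a sample multiplied by its TMM factor. Means are given with the SD of 4 samples and log2 fold changes with a standard error. Gene lists (36, with 946 symbols, of which 3 were not matched) were tested on log2 CPM with camera from limma 3.58.1, with a preset correlation of 0.01, and with fry, adjusted by Benjamini-Hochberg over the lists with at least 5 measured members. Members were also counted with p-values adjusted over the list alone. For genes with 1 to 3 counts in a group, ratios are given with exact 95% counting intervals.

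The main test, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Eif4ebp3, Eif4ebp1, Eif4ebp2 and Eif4e, then the 10 higher and 10 lower genes with the largest log2 fold changes among those with an adjusted p under 0.05, a mean of at least 1 CPM, no overlap between groups and an established symbol. It also named up to 4 changed members of each list with the smallest p-values. Exceptions are AC115631.1, the members said to move against their list unless the rule named them, Alb, Trf, Ghr and Ddx3y, all chosen after their values were seen. Values of some single genes are not reported here. Of the 159 genes the rule named, 51 share exon bases with another annotated gene, among them Apela, Vmn1r90, Tm7sf2, Ucp2, Elovl3, Irf7, Nr1i3, Bmp6, Alas2, Ndufs1 and Rps18, so their counts are uncertain where reads were not assigned by strand. Close paralogs share reads as well, in particular the Mup, Serpina1, Serpina3, Cyp2a, Cyp2c, Cyp3a, Cyp4a, Gsta, Gstm, Ugt2b, Hba, H2 and histone genes.

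Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter, a filter on the mean CPM, the replicate number or the letter of the sample code as a covariate, a minimum fold of 1.5 and leaving out each sample in turn. Total-count scaling, the addition of the assembled loci and the use of the samples coded C alone were chosen after the data were seen, as were the tests of 283 pathways of 15 to 300 genes from the authors' annotation and the division of the sex-dependent list into male- and female-biased genes. The same tests were tested on simulated data with 14513 genes. edgeR recovered 42.6% of genes changed 1.5-fold, 85.4% of those changed 2-fold, 100% of those raised 4-fold and 97.9% of those lowered to 0.25 of control, with 12 false calls, against 37 with DESeq2 and 11 with limma-voom. Only 47 to 49 of the simulated genes tested were changed at each fold, whereas 57.2% of the real genes were called. The simulated rates and false calls therefore do not carry over to the real calls.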

Results

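Liver RNA was sequenced from 2-month-old C57BL/6 mice that had received an adenovirus carrying a short hairpin RNA. In the knockdown group (n = 4) the hairpin was directed at Eif4ebp3, and in the control group (n = 4) at the bacterial gene lacZ, which mice do not have. Livers were collected 1 week after injection of 0.1 OD of virus, in the fasted state. Each sample was represented by estimated counts per gene, with total counts of 27079278, 26358495, 24371461 and 24774709 in control replicates 1 to 4 and 25330306, 27891857, 25651716 and 32389444 in knockdown replicates 1 to 4. The comparison asked which liver transcripts differed in abundance when Eif4ebp3 was knocked down.

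Eif4ebp3, which encodes a small protein that binds the cap-binding factor eIF4E and restrains translation initiation, fell by 3.24 ± 0.53 (SE) on the log2 scale, 9.48-fold, from 190 ± 101 to 20.1 ± 12.1 normalised CPM (SD, n = 4 each). The control samples held 289, 216, 204 and 49.3 CPM (replicates 1 to 4) and the knockdown samples 9.62, 13.9, 37.2 and 19.5 CPM, so each knockdown sample lay below each control, although control replicate 4 lay nearer the knockdown samples than the other controls did. The corresponding estimated counts were 6027, 4611, 3964 and 1080 against 305, 477, 1083 and 759. The adjusted p was 0.000379 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and the authors' deposited table lists a log2 fold change of -2.66. The gene (ENSMUSG00000090264) lies on chromosome 18 at 36664060 to 36665917 of the mm10 assembly, and its exons overlap those of AC115631.1, a readthrough gene at 36647860 to 36665917 on the same strand. Reads shared with AC115631.1 make the residual Eif4ebp3 level uncertain, since that gene held 21.9 ± 5.73 CPM in the controls and 13.9 ± 2.95 CPM in the knockdown samples (SD, n = 4 each).

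The related translation repressors moved in opposite directions. Eif4ebp1 (chromosome 8, 27260329 to 27276674) rose by 0.54 ± 0.09 (log2, SE), from 36.4 ± 3.21 to 53 ± 3.69 CPM, with an adjusted p of 0.000296 from edgeR. Eif4ebp2 (chromosome 10, 61428491 to 61452661) fell by 0.73 ± 0.10 on the log2 scale, from 272 ± 17.4 to 164 ± 22.7 CPM (adjusted p = 0.000123, edgeR), a change that was -0.17 and did not pass under total-count scaling. Eif4e itself (chromosome 3, 138526179 to 138559696) held 43 ± 3.58 CPM in the controls and 40.1 ± 2.64 CPM in the knockdown samples (SD, n = 4 each), and the difference of -0.10 did not pass the test (adjusted p = 0.322, edgeR), whereas under total-count scaling it was 0.47 and passed.

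**Figure D1:**
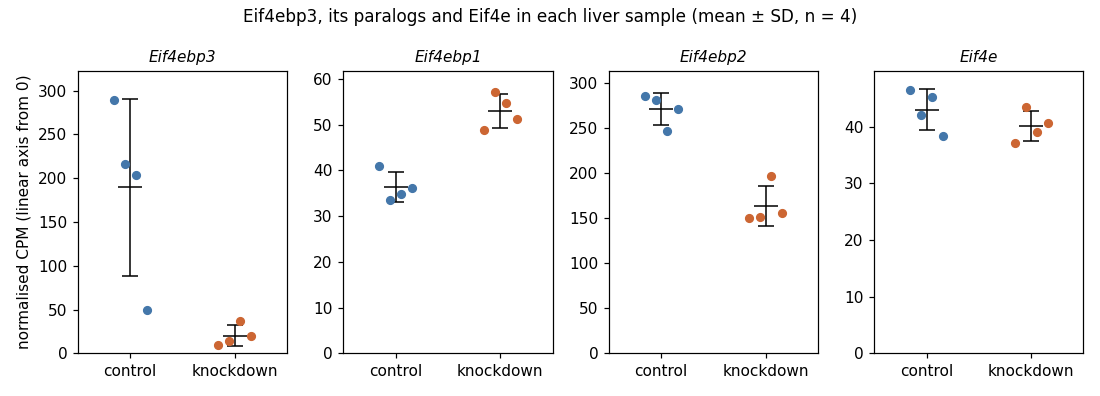
Normalised CPM (vertical axes, linear from 0) of Eif4ebp3, Eif4ebp1, Eif4ebp2 and Eif4e in the control and knockdown liver samples; points are samples, and bars are the mean ± SD of 4 samples. Control replicate 4 held 49.3 CPM of Eif4ebp3, against 204 to 289 CPM in the other controls and at most 37.2 CPM in the knockdown samples.

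Across the liver transcriptome, 8800 of 15375 genes tested (57.2%) differed between the groups, of which 4528 were higher and 4272 lower in the knockdown samples (51.5% higher). With a minimum of 1.5-fold, 3403 were higher and 2337 lower. Values of the groups did not overlap for 8008 genes (52.1%), where chance gives 2.86%. On the principal components of log2 CPM, PC1 held 76.7% of the variance and separated the groups, with scores of -74.5, -66.7, -64.8 and -40.8 for the controls and 70.8, 69.1, 49.2 and 57.7 for the knockdown samples. More genes had at least 1 count in the knockdown samples (21886 ± 502, SD, n = 4) than in the controls (20326 ± 269), and the 10 most abundant genes took 13% against 14.3% of the counts. The split of calls depended on the scaling: without normalisation factors the median of all genes shifted by 0.564 (log2), and 9831 genes were higher and 1187 lower (89.2% higher). All changes are therefore given relative to the median gene. The sample codes in the labels carry a letter, C for 3 samples and D for 1 sample of each group. What the letter stands for is not given in the sources used here. The samples coded C alone gave 4564 higher and 4275 lower genes, and those coded D are too few for a value. In the authors' deposited table, 2553 genes were marked as up and 1203 as down, with a fold change of at least 2, and 3298 of these 3756 genes passed the count filter used here. Of those, edgeR called 3295 with the same sign.

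**Figure D2:**
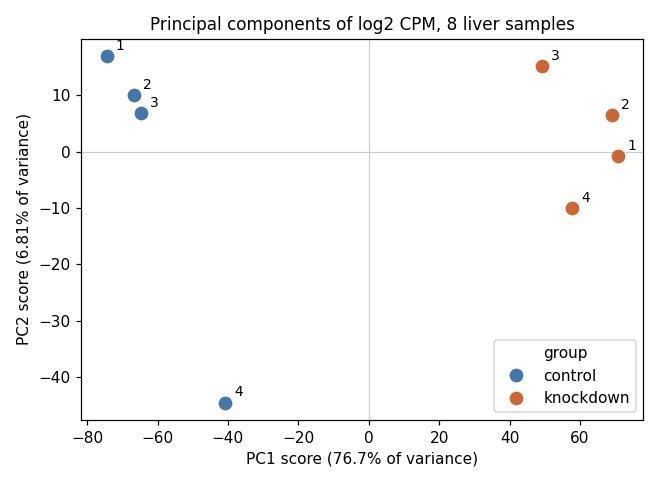
Scores of the 8 liver samples on the first principal components of log2 CPM (PC1 horizontal, 76.7% of the variance; PC2 vertical, 6.81%); numbers are replicates. Controls lie between -74.5 and -40.8 on PC1 and knockdown samples between 49.2 and 70.8.

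The 10 largest increases among eligible genes included the epithelial genes Sprr1a, Muc13 and Krt20. The cornified-envelope gene Sprr1a rose by 7.29 ± 0.35 (log2, SE) to 30.6 ± 7.01 CPM (SD, n = 4), the lipase gene Lipn by 7.43 ± 0.41, the mucin gene Muc13 by 6.75 ± 0.42, and the carbonyl reductase gene Cbr3 by 6.47 ± 0.24, from 0.863 ± 0.338 to 77.4 ± 15.1 CPM. Gstm3, a glutathione transferase gene, rose from 13.7 ± 8.99 to 1160 ± 183 CPM, and the imprinted long non-coding RNA H19 (chromosome 7, 142575529 to 142578143) from 1.72 ± 0.929 to 129 ± 41.8 CPM. Slc7a11, which encodes the cystine transporter subunit xCT, rose by 6.32 ± 0.48, or by 7.52 without control replicate 4, and the steroid hydroxylase gene Cyp2a4 by 5.93 ± 0.46, or by 6.54 without that sample. Apela held 1 count in all controls against 442 in the knockdown samples, a ratio of 275 (95% counting interval 49.1 to 10900, covering counting error only). That count was in control replicate 2, without which the fitted log2 fold change was 9.53, and the exons of Apela overlap those of Gm45886. Krt20 held 2 against 325 counts, a ratio of 101 (27.8 to 839). The rule admitted only genes that passed edgeR's test without overlap between groups, and the adjusted p of these 10 was at most 2.43e-06.

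The 10 largest decreases among eligible genes included 5 major urinary protein genes or pseudogenes. Moxd1 fell by 7.69 ± 0.51 on the log2 scale, from 124 ± 55.5 to 0.568 ± 0.456 CPM (SD, n = 4 each), and the log2 fold change was -8.46 without knockdown replicate 4. Mup7 fell from 14300 ± 4690 to 298 ± 133 CPM, Mup15 from 2700 ± 1030 to 66.1 ± 45.2 CPM, and the log2 fold changes of Mup21, Mup17 and the pseudogene Mup-ps8 were -5.89, -5.24 and -5.52. Values of single Mup genes are uncertain, since these near-identical copies on chromosome 4 can share reads. Hsd3b5, a hydroxysteroid dehydrogenase gene, fell by 5.82 ± 0.36. Vmn1r90, Nlrp5-ps and Obox4-ps3 had log2 fold changes of -6.70, -6.25 and -5.51. All lie within 14530652 to 14622479 on chromosome 7, and the exons of Vmn1r90 and Nlrp5-ps overlap, so their separate values are uncertain. The adjusted p of these 10 genes was at most 1.43e-05 (edgeR), and the rule again admitted only genes without overlap between groups.

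Genes of hepatic fat oxidation were lower. Of 30 genes of fatty acid oxidation and ketogenesis, 26 fell and 1 rose (1 and 26 also when adjusted over the list alone), with a median log2 fold change of -0.64. Under total-count scaling the median was -0.07, with 6 higher and 10 lower. Acsl1, which activates long-chain fatty acids, fell from 2240 ± 613 to 512 ± 38.9 CPM, the fatty acid transporter gene Slc27a2 from 2830 ± 234 to 764 ± 121 CPM, and Etfa, an electron-transfer flavoprotein subunit, by 0.83 ± 0.07 on the log2 scale, while the thioesterase gene Acot2 rose by 2.01 ± 0.15. Of 27 PPARA targets and fasting signals, 16 fell and 6 rose, as they did adjusted over the list alone, and their median of -0.52 became 0.05 under total-count scaling, where 7 rose and 7 fell. Ppara itself fell by 1.10 ± 0.09, Cyp4a32 by 2.80 ± 0.20 and Fgf1 by 1.64 ± 0.10, and Ucp2 rose by 1.78 ± 0.12. The other members of this list that rose were Cd36, Pdk4, Vldlr, Plin2 and Cidec. With camera's preset correlation the adjusted p was 8.73e-08 for fat oxidation and 0.0415 for PPARA targets, against adjusted p = 0.302 and adjusted p = 0.521 with an estimated correlation. In the same samples 28 of 30 macrophage, 32 of 35 T and NK cell and 20 of 26 stellate cell markers rose.

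Of 23 genes of fatty acid and triglyceride synthesis, 15 fell and 1, Mid1ip1, rose (15 and 1 adjusted over the list alone; median -0.66). Under total-count scaling 8 fell and 7 rose (median -0.07). Without control replicate 1 the number that rose was 0, and without control replicate 4 it was 2. Dgat2 fell by 1.03 ± 0.09, Acss2 by 1.04 ± 0.09, Acacb by 1.17 ± 0.11 and the desaturase gene Fads1 by 0.82 ± 0.08. Of 25 cholesterol synthesis genes, 12 fell and 2 rose, among them Dhcr7 (12 and 2 adjusted over the list alone; median -0.25, but 0.33 under total-count scaling, where 13 rose and 5 fell). Tm7sf2 fell by 1.69 ± 0.13, Hsd17b7 by 1.86 ± 0.16, Ebp by 0.92 ± 0.10 and Stard4 by 0.90 ± 0.09. The camera adjusted p was 0.00249 for fat synthesis (adjusted p = 0.266 with an estimated correlation) and 0.0338 for cholesterol synthesis (adjusted p = 0.553 with an estimated correlation). In the same knockdown samples 28 of 30 macrophage markers rose. Mid1ip1 and Dhcr7, like the other members named here as moving against their list, were chosen after their values were seen.

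Bile acid and glucose metabolism genes were lower, by less under total-count scaling, in the samples in which 20 of 26 stellate cell markers rose. Of 23 genes of bile acid synthesis and transport, 18 fell and 2, Abcc3 and the nuclear receptor gene Nr0b2, rose (18 and 2 adjusted over the list alone; median -0.70; camera adjusted p = 1.37e-06, and adjusted p = 0.266 with an estimated correlation). Under total-count scaling 11 of the bile acid genes fell and 4 rose (median -0.14). The uptake transporter gene Slco1a1 (chromosome 6, 141907282 to 141946962) fell from 259 ± 39.2 to 8.09 ± 2.77 CPM, the bile salt transporter gene Slc10a1 from 426 ± 32.8 to 78.4 ± 16.8 CPM, and the sterol 12-alpha-hydroxylase gene Cyp8b1 from 1180 ± 213 to 135 ± 41.4 CPM (SD, n = 4 each). Of 25 genes of gluconeogenesis and glycogen, 19 fell and 2, Ugp2 and Pgm2, rose (19 and 2 adjusted over the list alone; median -0.82; camera adjusted p = 0.000247, and adjusted p = 0.266 with an estimated correlation). For gluconeogenesis and glycogen 14 fell and 7 rose under that scaling (median -0.25). Fbp1, fructose-1,6-bisphosphatase, fell by 1.57 ± 0.14, the pyruvate carboxylase gene Pcx by 0.81 ± 0.09, Got1 by 2.29 ± 0.27 and the glycogen-targeting subunit gene Ppp1r3b by 1.66 ± 0.14. Of 20 insulin and FoxO targets, 10 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.45, but 0.12 under total-count scaling, where 5 rose and 5 fell). Without control replicate 3, 9 of these targets fell and 1 rose. Insr fell by 1.17 ± 0.08, Igf1 by 1.65 ± 0.14, Bcl6 by 1.53 ± 0.17 and Klf15 by 1.62 ± 0.19. For these targets the camera adjusted p was 0.00755, and adjusted p = 0.302 with an estimated correlation.

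Of 44 nuclear-encoded subunits of oxidative phosphorylation, 43 fell and 0 rose (43 and 0 adjusted over the list alone; median -0.50, but 0.06 under total-count scaling, where 12 rose and 1 fell). In the same samples markers of macrophages, T and NK cells and stellate cells rose. Sdha fell by 0.63 ± 0.07, Ndufs1 by 0.75 ± 0.08, Uqcrfs1 by 0.71 ± 0.08 and Uqcrb by 0.63 ± 0.07, and none of these 4 passed under total-count scaling. All 13 mitochondrially encoded genes fell, also when adjusted over the list alone, with a median of -0.93 that was -0.37 under total-count scaling, where 8 fell. The transcript of mt-Nd2 fell from 5590 ± 327 to 2540 ± 373 CPM, mt-Atp6 from 932 ± 98.8 to 444 ± 37.7 CPM, mt-Nd6 by 1.01 ± 0.12 and mt-Atp8, which overlaps mt-Atp6, by 0.98 ± 0.10. The camera adjusted p was 7e-10 for the nuclear-encoded and 1.48e-06 for the mitochondrially encoded genes, against adjusted p = 0.349 and adjusted p = 0.29 with an estimated correlation.

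Eif4ebp3 acts on the translation machinery. Of 47 cytosolic ribosomal protein genes, 5 rose and 4 fell (2 and 1 adjusted over the list alone) and the median was 0.01. Without control replicate 4, 2 rose and 7 fell. The number that rose was 2 or 3 without control replicate 1 or 2 or knockdown replicate 2 or 3. Rpl12 rose by 0.59 ± 0.13 and Rps20 by 0.35 ± 0.08, and Rps27 and Rps18 fell by 0.37 ± 0.09 and 0.27 ± 0.08 but rose by 0.20 and 0.31 under total-count scaling, where all 47 were higher. Of 38 translation factors and mTORC1 pathway genes, 15 fell and 6 rose (15 and 6 adjusted over the list alone; median -0.13, but 0.44 under total-count scaling, where 27 rose and 1 fell). Deptor, an inhibitor of mTOR, fell by 1.68 ± 0.10, from 205 ± 18.4 to 63.9 ± 6.95 CPM. Eif4a2, Pdcd4 and Eif4b fell by 0.80, 0.68 and 0.63, calls that were lost under total-count scaling. In the same samples 28 of 30 macrophage, 32 of 35 T and NK cell and 20 of 26 stellate cell markers rose. The camera adjusted p was 0.797 for the ribosomal proteins and 0.0374 for the translation factors (adjusted p = 0.393 with an estimated correlation).

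Of 27 amino acid response genes governed by ATF4, 13 rose and 6 fell (15 and 6 adjusted over the list alone; 21 and 3 under total-count scaling; median 0.70; camera adjusted p = 0.012, and adjusted p = 0.266 with an estimated correlation). The 6 that fell were Asns, Atf5, Cbs, Cebpb, Cth and Shmt2. Another 6 members, counted apart from direction, also stand in other lists, among them Gdf15 and Sesn2 in the p53 list. The serine synthesis gene Psat1 rose by 2.58 ± 0.19, Gdf15, a stress-induced secreted factor, from 5.55 ± 2.32 to 42.8 ± 2.3 CPM, and Sesn2 by 0.92 ± 0.10. Of 23 genes of the unfolded protein response of the endoplasmic reticulum, 11 fell and 1, Sec61b, rose (11 and 1 adjusted over the list alone; median -0.35, but 0.22 under total-count scaling, where 9 rose and 2 fell). The camera adjusted p was 0.00778, and adjusted p = 0.521 with an estimated correlation. Without knockdown replicate 3, 17 of these genes fell. The chaperone genes Hsp90b1 and Calr fell by 0.91 ± 0.13 and 0.61 ± 0.12, and Sel1l and Dnajc3 by 0.84 and 0.76. The calls of Calr and Dnajc3 were lost under total-count scaling. Of 33 autophagy and lysosome genes, 15 fell and 8 rose (15 and 8 adjusted over the list alone; median -0.16, but 0.41 under total-count scaling, where 20 rose and 6 fell). The list did not pass camera (adjusted p = 0.137). The lysosomal hydrolase genes Hexa and Ctsd rose by 0.92 ± 0.07 and 0.82 ± 0.08, and Lamp2 and Ulk1, which starts autophagy, fell by 0.88 ± 0.08 and 0.93 ± 0.07. Markers of macrophages, T and NK cells and stellate cells rose in the samples of these comparisons too.

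Targets of the oxidative stress factor NRF2 rose in the samples in which 28 of 30 macrophage, 32 of 35 T and NK cell and 20 of 26 stellate cell markers rose. Of 24 measured, 22 rose and 1, Gclm, fell (22 and 1 adjusted over the list alone; 24 and 0 under total-count scaling; median 1.71; camera adjusted p = 1.61e-09, and adjusted p = 0.266 with an estimated correlation). Besides Cbr3, the sulfiredoxin gene Srxn1 rose from 54.5 ± 4.12 to 296 ± 38.1 CPM, the pentose phosphate enzyme gene Pgd from 37 ± 6.13 to 169 ± 19.3 CPM, and Gstm1 from 547 ± 145 to 4050 ± 230 CPM (SD, n = 4 each). Cytochrome P450 and drug metabolism genes went both ways, with 13 of 39 higher and 18 lower (13 and 18 adjusted over the list alone). Their median of -0.24, opposite in sign to their mean of 0.35, became 0.34 under total-count scaling, where 16 rose and 14 fell. The list did not pass camera (adjusted p = 0.218). Cyp2c54, Cyp2c50 and Ugt2b1 fell by 3.81 ± 0.19, 2.77 ± 0.15 and 2.69 ± 0.11, and Gsta4 rose by 2.26 ± 0.14. The Cyp2c, Ugt2b, Gsta and Gstm genes are close copies of each other, so the split of reads within each family is uncertain.

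Genes with sex- and growth hormone-dependent expression showed the lowest median of the 36 lists. Of 34 measured, 27 fell and 3, Cyp2a4, Cyp2b9 and Cyp3a41a, rose (27 and 4 adjusted over the list alone; 24 and 6 under total-count scaling), with a median of -2.06 (camera adjusted p = 7.31e-09, and adjusted p = 0.266 with an estimated correlation). The fatty acid elongase gene Elovl3 (chromosome 19, 46131897 to 46135694) fell from 626 ± 122 to 36 ± 5.34 CPM, Mup3 from 6690 ± 915 to 442 ± 88.1 CPM and Cyp4a12a from 530 ± 26.9 to 138 ± 5.94 CPM. All 19 genes of this list that are known as male-biased fell (median -3.92), whereas 3 of 7 measured female-biased genes rose and 2 fell; this division of the list was made after the data were seen. Markers of macrophages, T cells and stellate cells rose in the same samples.

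Hepatocyte products and periportal markers were lower in the knockdown livers, in which markers of macrophages and stellate cells were higher. Of 27 hepatocyte secretory products, 25 fell and 0 rose (25 and 0 adjusted over the list alone; 18 and 3 under total-count scaling; median -1.06; camera adjusted p = 9.57e-10, and adjusted p = 0.302 with an estimated correlation). Itih1 fell by 1.99 ± 0.14 and, with reads that its copies can share, Serpina1d by 2.76 ± 0.19. The exceptions were Alb (0.04, adjusted p = 0.83, edgeR) and Trf (0.18, adjusted p = 0.193, edgeR). Of 22 periportal genes, 17 fell and 3, Cdh1, Ctsc and Hsd17b13, rose (17 and 3 adjusted over the list alone; median -1.34; camera adjusted p = 5.37e-05, and adjusted p = 0.349 with an estimated correlation). Pigr fell from 1140 ± 109 to 216 ± 40.6 CPM and Cyp2f2 from 1650 ± 97.3 to 470 ± 93 CPM. Of 22 pericentral genes, 12 fell and 2, Cyp2a5 and Slc1a4, rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.00284, and adjusted p = 0.266 with an estimated correlation), and the median of -0.48 became 0.09 under total-count scaling, where 4 rose and 8 fell. Cyp2e1 fell from 5740 ± 1090 to 1270 ± 188 CPM, Rgn by 1.36 ± 0.08 and the receptor gene Nr1i3 by 1.58 ± 0.13. Of 32 acute phase genes, 16 fell and 9 rose (16 and 10 adjusted over the list alone; median -0.55, but 0.01 under total-count scaling, where 14 rose and 7 fell). Camera did not call this list (adjusted p = 0.167). Crp and the fibrinogen gene Fgb fell by 1.64 ± 0.14 and 1.15 ± 0.12, and Lcn2 rose from 20.2 ± 7.42 to 320 ± 57.7 CPM. Of 24 circadian clock genes, 13 fell and 5 rose (13 and 5 adjusted over the list alone; median -0.46, but 0.11 under total-count scaling, where 7 rose and 3 fell). The list did not pass camera (adjusted p = 0.0537). Without control replicate 1, 2 or 3 or knockdown replicate 4, 3 clock genes rose. Tef, Per2 and Hlf fell by 1.00 ± 0.10, 0.98 ± 0.11 and 1.10 ± 0.14.

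**Figure D3:**
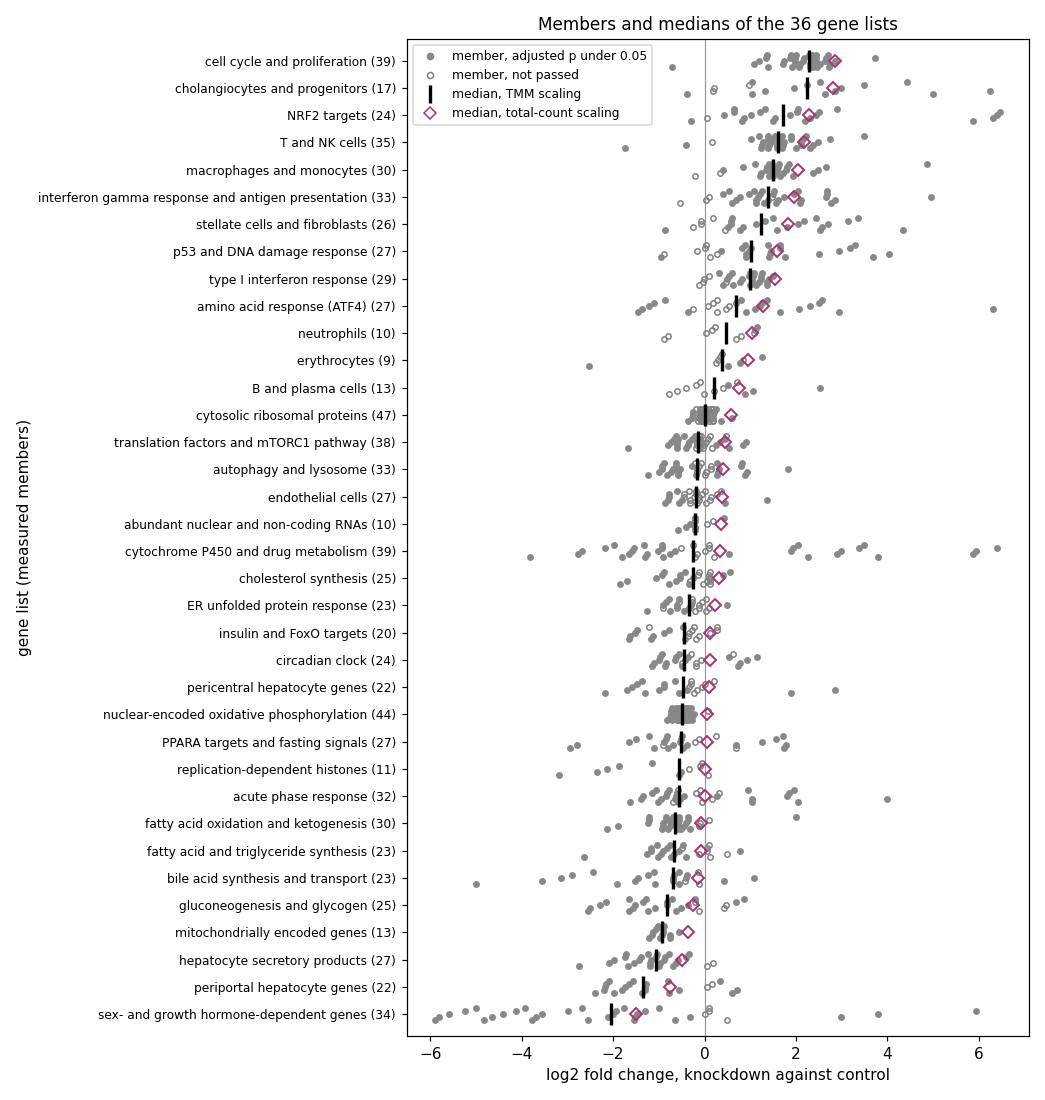
Log2 fold change of knockdown against control (horizontal axis) for the members of 36 gene lists (vertical axis, measured members in parentheses); filled points passed the test, open points did not, black bars are list medians and diamonds are medians under total-count scaling. Medians run from -2.06 for sex- and growth hormone-dependent genes to 2.29 for cell cycle genes, and total-count scaling shifts each of them upward, turning several lower lists, such as nuclear-encoded oxidative phosphorylation, to a median above 0.

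Cell cycle genes showed the highest median of all lists, 2.29, in the samples in which 28 of 30 macrophage, 32 of 35 T and NK cell and 20 of 26 stellate cell markers rose. Of 39 measured, 38 rose and 1, Tk1, fell (38 and 1 adjusted over the list alone; 38 and 0 under total-count scaling; camera adjusted p = 7e-13, and adjusted p = 0.302 with an estimated correlation). The G1 cyclin genes Ccnd1 and Ccne1 rose from 10.2 ± 1.5 to 51.8 ± 8.04 CPM and from 1.39 ± 0.416 to 18.5 ± 2.99 CPM, the replication helicase gene Mcm6 from 13.9 ± 3.77 to 93.4 ± 6.73 CPM and the ribonucleotide reductase gene Rrm1 from 21.8 ± 1.72 to 56.5 ± 5.28 CPM (SD, n = 4 each). Of 27 genes of the p53 and DNA damage response, 20 rose and 1, Ei24, fell (20 and 1 adjusted over the list alone; median 1.02; camera adjusted p = 4e-06, and adjusted p = 0.266 with an estimated correlation). Without control replicate 2 or 4, 2 of the p53 genes fell. Psrc1, Phlda3, Zmat3 and the apoptosis effector gene Bax rose by 4.04 ± 0.19, 3.28 ± 0.18, 1.66 ± 0.09 and 1.42 ± 0.10. Replication-dependent histone genes did not follow the cell cycle list: 7 of 11 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.55, but 0.00 under total-count scaling, where 0 rose and 5 fell). The camera adjusted p of the histone list was 0.00688, and adjusted p = 0.266 with an estimated correlation. Hist1h1c fell from 170 ± 14.3 to 76.9 ± 12.4 CPM and Hist2h2aa1 from 14.8 ± 2.9 to 4 ± 0.814 CPM, though histone copies can share reads. Of 10 abundant nuclear and non-coding RNAs, 3 fell and 1, Snhg1, rose (3 and 1 adjusted over the list alone; median -0.21, but 0.36 under total-count scaling, where 3 rose and 0 fell). Camera did not call these RNAs (adjusted p = 0.295). The rise of Snhg1 (0.44) was lost without control replicate 1 or 3 or knockdown replicate 2 or 4 and with the samples coded C alone. The fall of Meg3 (-0.58) was lost without any sample but control replicate 4 or knockdown replicate 4, with upper-quartile or total-count scaling and with the replicate block. Malat1 and Gas5 fell by 0.40 ± 0.08 and 0.31 ± 0.07 but were at 0.17 and 0.26 under total-count scaling.

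Immune genes were higher in the knockdown livers. Of 33 genes of the interferon gamma response and antigen presentation, 29 rose and 0 fell (29 and 0 adjusted over the list alone; median 1.38). The MHC class II genes Cd74, H2-Aa and H2-Eb1 rose by 2.85 ± 0.19, 2.66 ± 0.19 and 2.67 ± 0.21 and the ubiquitin-like gene Ubd from 1.7 ± 0.857 to 52.6 ± 15.6 CPM. Of 29 type I interferon response genes, 24 rose and 0 fell (24 and 0 adjusted over the list alone; median 0.99). Bst2, Ifi27l2a, Oas1a and Irf7 rose by 0.99, 1.25, 1.20 and 0.81. Of 30 macrophage and monocyte markers, 28 rose and 0 fell (28 and 0 adjusted over the list alone; median 1.49): Gpnmb rose from 1.7 ± 0.426 to 49.8 ± 11.2 CPM, Trem2 from 1.74 ± 0.166 to 11 ± 1.53 CPM and the complement gene C1qa from 51.4 ± 4.2 to 132 ± 4.12 CPM. Of 35 T and NK cell markers, 32 rose and 2, Cd4 and Zap70, fell (32 and 2 adjusted over the list alone; 32 and 1 under total-count scaling; median 1.61). Without control replicate 1, 2 or 3 or knockdown replicate 1, 2 or 4, only 1 T and NK cell marker fell. The T cell receptor genes Trac and Trbc2 rose by 2.48 ± 0.30 and 2.22 ± 0.27 and the NK receptor gene Klrk1 by 1.40 ± 0.18, whereas Cd4 fell from 6.99 ± 0.55 to 2.07 ± 0.341 CPM. The camera adjusted p was 6.83e-09, 5.93e-06, 8.66e-11 and 2.25e-07 for these 4 lists in that order, against adjusted p = 0.349, 0.349, 0.266 and 0.349 with an estimated correlation.

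Of 13 B and plasma cell markers, 4 rose and 0 fell (3 and 0 adjusted over the list alone; 7 and 0 under total-count scaling; camera adjusted p = 0.367). Cr2, Bank1 and Cd22 rose by 2.53 ± 0.42, 1.05 ± 0.26 and 0.88 ± 0.24. The call of Ighm (0.51) was lost with the replicate number as a block and without control replicate 1, 2 or 3 or knockdown replicate 1, 2 or 4, and was lowest (0.39) without control replicate 1. Without knockdown replicate 3, 1 B cell marker fell. Of 10 neutrophil markers, 1, the receptor gene Csf3r, rose by 1.14 ± 0.18 and 0 fell (1 and 0 adjusted over the list alone; 5 and 0 under total-count scaling; camera adjusted p = 0.295). The number of neutrophil markers that rose was 3 without control replicate 4 or knockdown replicate 3 and 2 without control replicate 2, and 1 fell without control replicate 3.

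Among the other cell types of the liver, markers moved apart. Of 26 stellate cell and fibroblast markers, 20 rose and 1, Ecm1, fell (20 and 1 adjusted over the list alone; 24 and 0 under total-count scaling; median 1.23; camera adjusted p = 3.8e-05, and adjusted p = 0.349 with an estimated correlation). Without control replicate 4, 17 of the stellate markers rose and 2 fell. The collagen genes Col1a1 and Col3a1 rose from 12.5 ± 4.35 to 128 ± 36.5 CPM and from 27.8 ± 8.16 to 246 ± 70.4 CPM, and Col1a2 and Col5a1 by 2.52 ± 0.19 and 2.04 ± 0.15. Of 17 cholangiocyte and progenitor markers, 13 rose and 1 fell (13 and 1 adjusted over the list alone; 16 and 0 under total-count scaling; median 2.25; camera adjusted p = 2.43e-05, and adjusted p = 0.259 with an estimated correlation). Without control replicate 2, 3 or 4 or knockdown replicate 1 or 2, 0 of these markers fell by edgeR. Besides H19, alpha-fetoprotein (Afp) rose from 1.16 ± 0.316 to 37.2 ± 14 CPM, and Cd24a and Sox4 rose by 2.84 ± 0.21 and 2.63 ± 0.22. Of 27 endothelial markers, 7 fell and 2, Clec1b and Cdh5, rose (6 and 1 adjusted over the list alone; median -0.19, but 0.39 under total-count scaling, where 9 rose and 0 fell). The list did not pass camera (adjusted p = 0.165). Without knockdown replicate 1, 14 endothelial markers fell, and without that sample, control replicate 1 or 3 or knockdown replicate 2, 1 rose. Bmp6 and Flt1 fell by 0.61 ± 0.15 and 0.80 ± 0.22, calls lost under total-count scaling, and Clec4g by 0.49 ± 0.14, a value that was 0.08 under that scaling. The values of Flt1 overlapped between groups. Of 9 erythrocyte genes, 3 rose and 1, the haem synthesis gene Alas2, fell (3 and 1 adjusted over the list alone; 7 and 1 under total-count scaling; camera adjusted p = 0.331), and the median was 0.39 while fry gave the opposite direction. The number of erythrocyte genes that rose was 1 without control replicate 1 or 3 or knockdown replicate 2 and 6 without control replicate 2. Alas2 fell from 89.2 ± 10.6 to 15.4 ± 2.25 CPM and Tfrc rose by 0.77 ± 0.14.

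**Figure D4:**
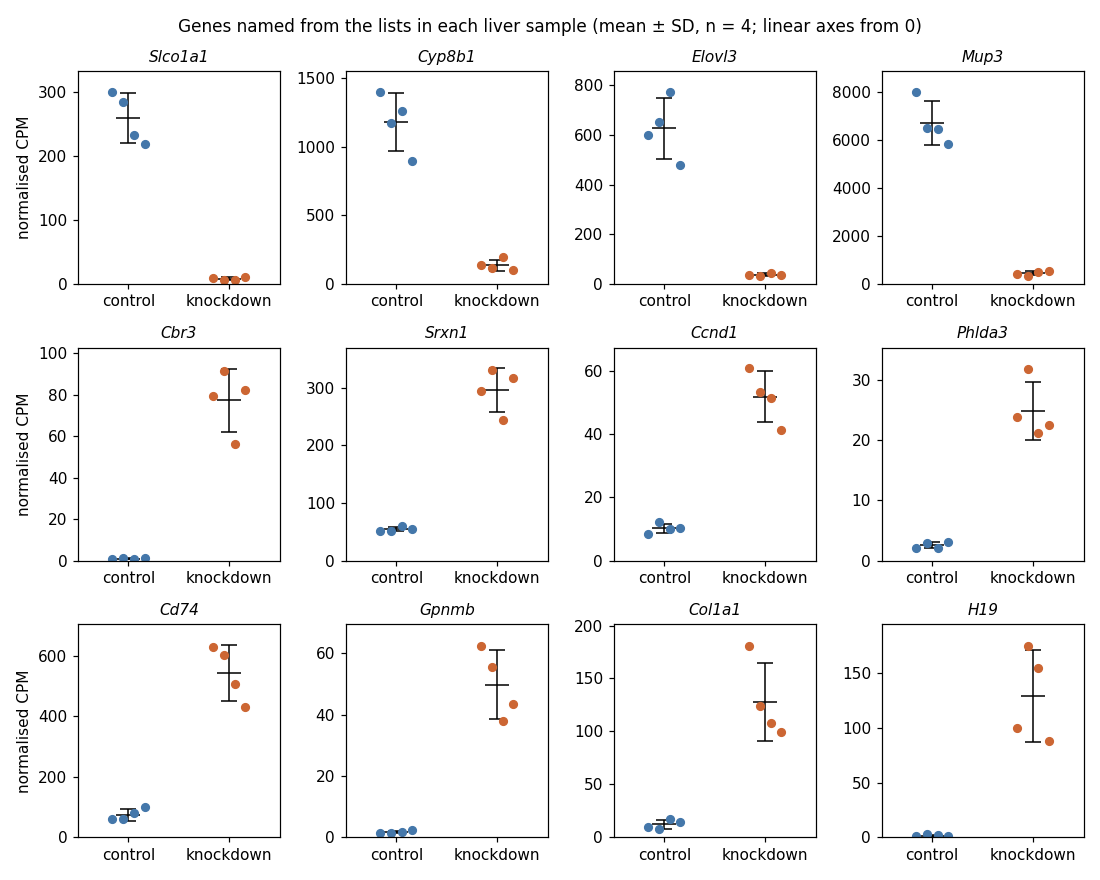
Normalised CPM (vertical axes, linear from 0) of 12 genes named from the lists, in the control and knockdown liver samples; points are samples, and bars are the mean ± SD of 4 samples. In each panel the groups do not overlap; for example Elovl3 fell from 626 to 36 CPM and Gpnmb rose from 1.7 to 49.8 CPM.

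Over the 36 lists, camera with its preset correlation called 26, 10 higher and 16 lower, and with an estimated correlation it called 0 (6 lists had an unadjusted p under 0.05). The directional p of fry, which asks whether the genes of a list move on balance in 1 direction, called 30 lists, and its mixed p, which asks whether they change in either direction, called 35; neither compares a list with other genes.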

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

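The tests of a label swap, of the cell types, of the sex of the mice, of hepatocyte RNA and of the Eif4ebp3 level in control replicate 4 were chosen only after the result was seen.

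In 26 of 326 groups of 4 samples, a sample lay far from the other 3 of its group by Dixon's test, where chance gives about 1 in 20 independent groups. These groups share the same samples and are not independent, so that rate is only a guide. In control replicate 4 these were Slc7a11 at 0.411 CPM, Etfa at 279 CPM, Gsta4 at 34.8 CPM, Rgn at 216 CPM and Rrm1 at 24.3 CPM. In control replicate 3 Hsp90b1 stood apart at 1200 CPM and Hist1h2bc at 116 CPM, in control replicate 1 Mup15 at 4240 CPM, and in control replicate 2 Apela at 0.0467 CPM, the only count of that gene in a control. A lone count in a group always stands apart by this test. Knockdown replicate 3 stood apart for Eif4ebp2 (197 CPM), Gstm3 (889 CPM), Slc27a2 (944 CPM), Ebp (88.6 CPM), Sel1l (160 CPM), Hsp90b1 (976 CPM) and Calr (949 CPM). In knockdown replicate 4 the genes were Etfa at 179 CPM, Fgf1 at 59.7 CPM, Eif4a2 at 152 CPM, Ndufs1 at 97.8 CPM and mt-Nd2 at 3090 CPM. In knockdown replicate 1 they were Acot2 at 63.6 CPM, Lcn2 at 234 CPM, Bank1 at 6.63 CPM and Csf3r at 11.3 CPM, and in knockdown replicate 2 Tfrc at 103 CPM. Outside the annotated genes, the assembled loci held 1.02% of the counts in the knockdown samples and 0.746% in the controls. That share is of total counts, whereas with TMM factors, which differ between the groups, 65 of 418 such loci tested rose and 159 fell.

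The tests were repeated on other splits of the 8 samples. Of the 35 splits into 4 and 4, only 1, the real split, gave 8800 changed genes, and edgeR called 0 genes in each of the others, where up to 3193 genes had an unadjusted p under 0.05. The same held for the 4528 higher genes and the 4272 lower genes (1 split each, highest other 0). Each other split puts knockdown and control samples in both sets, so the group difference adds to the spread within each set. Their 0 calls therefore do not show what chance alone gives. The real split is 1 of 35, the smallest share these splits can give. For the gene lists, 6 of the 35 splits gave at least the 26 lists of the real split, and the highest other gave 30. The others among these 6 exchange 1 sample of each group and so keep part of the group difference, so this count does not show what chance alone gives. Splits that exchange 2 samples gave at most 20 lists.

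Control replicate 4 lay nearer the knockdown samples than the other controls did (PC1 score -40.8), with Eif4ebp3 at 49.3 CPM. A swap of labels with a knockdown sample is excluded, since its mean correlation with the other controls exceeded that with the knockdown samples by 0.0421, and no knockdown sample lay among the controls. Knockdown RNA mixed into this sample would need a share of 0.865 to give its Eif4ebp3 level. Genes at least 4-fold higher in knockdown gave a median share of 0.131 (95% interval of the median 0.118 to 0.149). Single genes among them ran from -0.0554 to 0.524 (5th to 95th percentile). Genes at least 4-fold lower gave a median of 0.258 and ran from -0.627 to 0.757. The Eif4ebp3 share lies above both ranges, which argues against mixing as the whole cause of that level. For the place of control replicate 4 between the groups, mixing cannot be told apart from a difference of the animal, because the shares from lower and from higher genes differed by 0.126 (0.0852 to 0.186), an interval that spans the bound of 0.1 set beforehand. The animal itself and the code letter D, which it shares with knockdown replicate 4, stay open.

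Markers of macrophages, T and NK cells and stellate cells rose together in the knockdown samples. The values argue against a lower share of hepatocytes raising all other cell types alike, since the macrophage median exceeded the endothelial median by 1.68 (95% interval 1.56 to 1.97). That interval covers the spread of list members and not the spread between mice. Cd4 also fell while Trac and Trbc2 rose. In the controls, however, Cd4 held 6.99 CPM, against 0.782 CPM of Trac and 1.21 CPM of Trbc2. Which cells the Cd4 RNA came from was not tested, so its fall says little about T cells. More of these cells, or more RNA of these genes per cell, stay open. The labels name 1 knockdown virus and 1 control virus, so a response to the particular hairpin or virus preparation was not separated from the loss of Eif4ebp3.

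All 19 male-biased genes fell, by more than the hepatocyte secretory products. Female mice in the knockdown group are excluded, since the Y-linked gene Ddx3y was at 47.4 CPM or more in each knockdown sample. The values argue against a general loss of hepatocyte RNA as the whole cause. The male-biased median lay below that of the secretory products, with a difference of -2.86 (95% interval -3.78 to -1.95). That interval covers the spread of list members, among them Mup copies that can share reads, and not the spread between mice. A lower response to growth hormone is only a hypothesis. The growth hormone receptor gene Ghr, chosen after its values were seen, fell from 351 ± 27.4 to 142 ± 8.94 CPM (adjusted p = 9.27e-07, edgeR, no overlap between groups). Most of its list fell (27 of 34 genes), as did hepatocyte secretory products (median -1.06), so its fall does not single out this hypothesis. The hypothesis was not tested here, and it stays open beside an effect of the particular hairpin or virus preparation.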

How the results depend on the processing

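Total-count scaling, the added assembled loci and the samples coded C alone were chosen only after the result was seen. The fold of Eif4ebp3 ranged from -3.73 to -2.67 over 19 alternatives, with adjusted p from 9.05e-07 to 0.00202. Of the 8800 changed genes, 8699 were shared with the same sign by DESeq2, 8675 by limma-voom and 5715 by total-count scaling. With a minimum of 1.5-fold, 5740 genes changed, 3403 higher and 2337 lower. A stricter threshold lowers both counts by construction, but it does not fix their balance. At 2-fold, 2375 were higher and 1083 lower, so the larger changes under TMM scaling were mostly increases. Under total-count scaling 9831 genes were higher and 1187 lower, since leaving out the normalisation factors moves all genes up. It reversed the sign of Eif4e (0.47), Rps27 (0.20), Rps18 (0.31), Clock (0.0139), Clec4g (0.0835), Malat1 (0.17), Gas5 (0.26) and Hist1h2bc (0.039) by the same shift. Which scaling is nearer to the amounts of RNA per cell was not tested. With an estimated correlation camera called 0 lists (6 with an unadjusted p under 0.05), against 26 with the preset correlation and 30 with fry. Estimated correlations reached 0.736 for the interferon gamma list and 0.708 for nuclear-encoded oxidative phosphorylation, against the preset 0.01. The amino acid response list lost its call at an estimate of -0.00238, so a higher correlation is not the whole cause. With an estimated correlation, camera also takes its degrees of freedom from the samples, and with the preset one from the far larger number of genes. How much each difference contributes was not tested. With the replicate number as a block, 8482 genes changed, with 26 lists and Eif4ebp3 at -3.15; the numbers do not pair the samples, as same-number correlations ran from -0.128 to 0.148. Leaving out each sample in turn gave 7855 to 9304 changed genes, 4091 to 4811 higher and 3764 to 4493 lower, with Eif4ebp3 from -3.73 to -2.97 and 24 to 27 lists. Of the named genes, 13 lost their call under total-count scaling and 6 in another alternative (Rps18, Ighm, Hba-a1, Slc4a1, Meg3 and Snhg1). Depth limits the genes with the fewest counts: 29 tested genes had at most 3 counts in all samples of a group, 5 of them 0.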

Other observations

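The pathway tests were chosen only after the result was seen. Among 283 pathways of 15 to 300 genes in the authors' annotation, some were picked for description. None of those named here was called by camera with an estimated correlation (adjusted p = 0.442 for oxidative phosphorylation and adjusted p = 0.406 for each of the others). In DNA replication 31 of 36 genes rose and 2 fell (median 1.12; camera adjusted p = 5.26e-08), in homologous recombination 23 of 39 rose and 3 fell, and in mismatch repair 17 of 22 rose and 3 fell. In glutathione metabolism 38 of 64 genes rose and 13 fell, and in the phagosome, the compartment for engulfed particles, 84 of 153 rose and 18 fell. Genes of cell adhesion (71 of 125 rose, 12 fell) and of apoptosis (79 of 139 rose, 22 fell) went mostly the same way.

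The pathways called lower included several of metabolism, and also Parkinson's and Alzheimer's disease, whose medians of -0.45 and -0.36 became 0.11 and 0.21 under total-count scaling. The oxidative phosphorylation pathway had nearly the values of Parkinson's disease: 100 of 136 genes fell and 12 rose, against 97 and 11 of 142. Its median of -0.46 became 0.11 under that scaling. Genes shared between these pathways were not counted, so they are not separate results. In complement and coagulation 60 of 93 genes fell and 17 rose (median -0.68, and -0.11 under total-count scaling; camera adjusted p = 2.38e-06, and adjusted p = 0.406 with an estimated correlation), in steroid hormone biosynthesis 50 of 79 fell and 11 rose (median -0.90, and -0.34 under that scaling), and in tryptophan metabolism 23 of 34 fell and 4 rose (median -0.68, and -0.12 under that scaling). In the peroxisome 55 of 79 genes fell and 10 rose, with a median of -0.45 that became 0.11 under total-count scaling. In the citrate cycle 20 of 28 fell and 2 rose, with a median of -0.46 that became 0.12 under that scaling. Camera called 88 pathways higher and 27 lower, and 0 in either direction with an estimated correlation.

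Knockdown replicate 3 had the most Eif4ebp3 of its group (37.2 CPM) and the lowest PC1 score of its group (49.2), while control replicate 4 had the least Eif4ebp3 of the controls (49.3 CPM) and the PC1 score nearest to the knockdown samples (-40.8). Median log2 fold changes by quintile of gene length, from the shortest to the longest, were -0.037, 0.02, 0.015, 0.024 and -0.041.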
